A study of Mus musculus with 8 samples.

How the data were processed

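Bladder RNA of mice was sequenced in 8 libraries, 4 labelled NeMO and 4 labelled Sham. Per the labels' protocols, RNA was extracted with Trizol, treated with DNase and checked on a Bioanalyzer, and polyA libraries were made with a directional kit and sequenced as single-end reads on an Illumina HiSeq instrument. The deposited files hold whole-number read counts per gene symbol, 1 file per library, and the submitters' processing notes name Trimmomatic, STAR, featureCounts and DESeq2 and the mm10 genome build, without versions. The annotation used for counting, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Without the strand setting, reads of overlapping antisense genes cannot be told apart, and genes with near-identical copies (ribosomal proteins, the major urinary proteins, Gapdh) are uncertain. All columns of counts were used as deposited, with 38926 symbols per library.

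Groups and replicate numbers come from the sample titles and the treatment label. The batch of each library comes from the mark in its submitted file name and is crossed with treatment: batch 1 holds 2 NeMO and 3 Sham libraries and batch 2 holds 2 NeMO and 1 Sham library. Values in batch 2 alone therefore rest on a single Sham library, assumed to vary like the NeMO libraries beside it. Leaving out that library, Sham replicate 4, takes batch 2 out of the group contrast, so that fit repeats the comparison within batch 1. Library totals ran from 27212499 to 36375313 counts, and the biological coefficient of variation over all genes tested was 0.186. At 1 CPM a gene had 27.2 to 36.4 reads per library, so genes near 0.2 CPM, such as Inhba in Sham, rest on few reads.

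Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr on the group with its defaults (minimum count 10, minimum total count 15), which left 16370 genes, and libraries were scaled by TMM. The test was edgeR's quasi-likelihood F-test (robust fit) with batch and group as terms, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A log2 fold change is NeMO minus Sham, and CPM are counts scaled to a common library size after TMM. Before the data were examined, 42 gene lists (pathways and cell type markers of the bladder and its neighbours) were written down, of which the 41 other than the sex-linked genes were tested, each with at least 3 tested members. This was done with limma's camera on log2 CPM (prior count 2) with the same terms and a preset inter-gene correlation of 0.01, adjusted over the 41 lists, and again with an estimated correlation and with fry. The list of sex-linked genes was given as values only. A gene that stands in more than 1 list counts in each, such as the keratin and uroplakin genes that the mesothelial and urothelial lists share.

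The rule for named genes was also fixed before the data were examined. It takes, among genes past the threshold with a mean of at least 1 CPM and no overlap between the groups, leaving out gene models and pseudogenes, the 12 largest increases, the 12 largest decreases and the 6 smallest p. For each list described it takes up to 4 members past the threshold with the smallest p or, where there are none, the 2 most abundant as values. It always takes Acta2, Col1a1, Col3a1, Tgfb1, Tnf, Nppb, Hbegf, Myc, Jun, Fos, Chrm3 and Gapdh. Some genes that the rule takes are not reported here. Chosen after their values were seen were Mup10, Fn1, Mfap4, Eln, Col12a1, Postn, Cpa3, Cma1, Tpsb2, Mcpt4, Mrgprb1, Cox6c, Ifi27l2a, Isg15, Cxcl10, Upk2, Krt20, Col17a1, Bdnf, Ptpn14, Kcnma1, Tgfb2, Pcp4, Itgbl1, Cthrc1, Sfrp4, Htr1b, Adra1d, Tacr2, Gria1, Galr2, Grem1, Adipoq, Cfd and Fst.

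Positions, transcript lengths and GC content come from GENCODE release M21 on GRCm38, the assembly that mm10 names. Of the 38926 symbols, 35656 matched directly and 1788 through a RefSeq synonym, and 98.9% of the genes tested had a length. The length and GC correction fitted a spline (4 degrees of freedom each) to every library's deviation from the gene mean and removed it.

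The gene and list tests were tested on simulated data with the means and library sizes of the real libraries, in 5 runs over 16370 genes. Of genes changed by a log2 fold change of 0.5, 1 and 2, the test found 26.6% (89 of 335), 68.4% (229 of 335) and 90.3% (298 of 330), with 59 false calls over all runs. A list shifted by 0.5 was found in 5 of 5 runs, and 0 of 200 unchanged lists were called. Simulated genes varied independently, whereas members of real lists can move together (estimated correlation 0.84 for interferon response genes). The runs therefore do not show how often camera calls unchanged lists of correlated genes. The libraries were also compared pairwise within each group, and every pair differed by more than sampling noise. Comparisons of library quantities used two-sided exact permutation tests, adjusted over 6 quantities.

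Alternatives fixed before the data were examined were a fit without batch, a fit with the replicate number as a block, DESeq2 size factors, upper-quartile scaling, no filter, a stricter filter (at least 1 CPM in at least 4 libraries), DESeq2's Wald test, limma voom, a non-robust fit, each batch alone, each library left out, an estimated correlation, fry and a prior count of 0.5. A threshold of 0.1 and the length and GC correction were chosen after seeing the data.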

Results

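Whole bladder tissue of mice was profiled by polyA RNA sequencing in a surgical model of partial bladder outlet obstruction that spares the nerves, abbreviated NeMO, and in sham-operated animals. The series holds 4 NeMO libraries and 4 Sham libraries. Library totals ran from 27212499 to 36375313 counts, from 29451800 to 36375313 in NeMO and from 27212499 to 33459048 in Sham. Between 20186 and 21248 genes had at least 1 count in a library. Each library carries a batch mark: batch 1 holds 2 NeMO and 3 Sham libraries, and batch 2 holds 2 NeMO libraries and 1 Sham library, replicate 4. Every value in batch 2 alone thus rests on that single Sham library, and every fit without Sham replicate 4 is in effect the comparison within batch 1. The labels do not say that each library came from its own animal, so the p-values measure the spread between these samples. The single comparison the design implies is NeMO against Sham, which asks which bladder transcripts differ after obstruction. The series title also names a comparison with human signatures, and human samples were not analysed here.

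Obstructed bladders held more of the transcripts for the activin A subunit Inhba, which was close to the detection floor in Sham. Inhba measured 2.73 ± 1.03 CPM (counts scaled to a common library size) in NeMO and 0.249 ± 0.0639 in Sham (mean ± SD, n = 4 each, log2 fold change 3.49, SE 0.39, edgeR adjusted p = 0.0175). Transcripts of Tnnt2, the cardiac isoform of troponin T, fell from 302 ± 117 CPM in Sham to 80.9 ± 19.3 in NeMO (log2 fold change −2.00, SE 0.20, edgeR adjusted p = 0.0175). The plasma membrane calcium pump gene Atp2b3 rose from 1.01 ± 0.291 to 8.28 ± 3.84 CPM (log2 fold change 3.20, SE 0.30), and the noradrenaline transporter gene Slc6a2 rose from 7.89 ± 1.84 to 22.4 ± 4.66 CPM (log2 fold change 1.56, SE 0.20), with edgeR adjusted p = 0.0175 and 0.0453.

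These genes belong to a set of 12 that passed an adjusted p of 0.05 among 16370 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 7 higher and 5 lower in NeMO. Of the 12, 7 differed by at least 2-fold. The smaller increases were in Fam211b (listed as Lrrc75b in GENCODE, log2 fold change 1.07, SE 0.12), Btbd7 (0.71, SE 0.10) and the serine protease gene Prss23 (0.69, SE 0.09). Besides Tnnt2, the genes that fell were Cpe, which encodes the prohormone-processing carboxypeptidase E (334 ± 35.5 CPM in Sham, 183 ± 7.66 in NeMO, log2 fold change −0.89, SE 0.09), the adenosine receptor gene Adora2b (1.75-fold lower, log2 fold change −0.81, SE 0.11) and the extracellular matrix gene Efemp1 (175 ± 11.6 against 108 ± 14.1 CPM, log2 fold change −0.64, SE 0.07). Another gene that fell, Mup10 (log2 fold change −1.80, SE 0.25), lies outside the rule for named genes because its libraries overlap, and it was singled out after its values were seen. Mup10 belongs to the major urinary protein family of near-identical copies, so the assignment of its reads is uncertain.

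All 12 genes moved in the same direction in batch 1 and in batch 2 when each was fitted alone, and for the 11 genes other than Mup10 the 4 NeMO and 4 Sham values did not overlap. Because the 12 were selected with these same libraries, both patterns were likely beforehand and are not independent support. Across all genes tested, 1341 (8.19%) showed no overlap between the groups, against 2.86% on average over random groupings of 4 and 4. Genes move together between libraries, so the share in 1 grouping can lie far from that average. The difference therefore does not exclude chance. At an unadjusted p under 0.05, 1535 genes were higher and 1497 lower in NeMO. The number of genes past the threshold changed when 1 library was left out. It was 652 without NeMO replicate 1 and 50 without NeMO replicate 2, each with all of the 12. It was 7 without NeMO replicate 3, of which 3 were among the 12. It was 3 without Sham replicate 1 (2 of the 12) and 4 without Sham replicate 2 (3 of the 12). Without Sham replicate 3 it was 11 (7 of the 12). It was 0 without NeMO replicate 4 (2549 in edgeR at an unadjusted p under 0.05). Batch 1 alone gave 0 genes (1756 at an unadjusted p under 0.05), as did the fit without Sham replicate 4 (1656), which repeats that comparison. DESeq2's Wald test on all libraries gave 865, the 12 among them. The fold changes moved less, with log2 values of 3.15 to 3.74 for Inhba and −2.26 to −1.80 for Tnnt2 when 1 library was left out. After a correction for transcript length and GC content, chosen after the data were seen, 9 of the 12 genes still passed, while Slc6a2 (1.45, edgeR adjusted p = 0.0578), Adora2b (−0.73, edgeR adjusted p = 0.0598) and Btbd7 (0.53, edgeR adjusted p = 0.0975) did not.

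**Figure D1:**
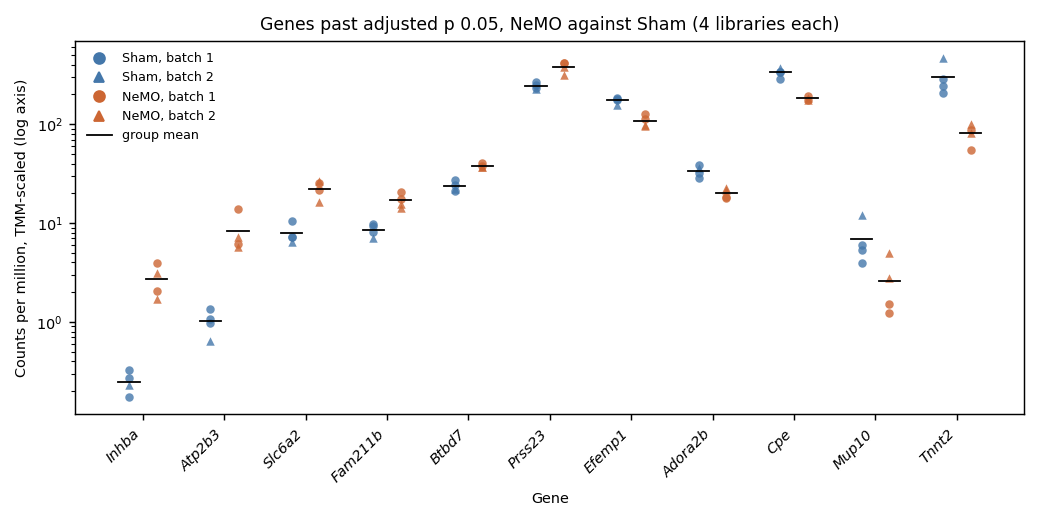
CPM (log axis) in each library for 11 of the 12 genes past the adjusted threshold, Sham on the left and NeMO on the right of each gene, with circles for batch 1, triangles for batch 2 and a black bar for the group mean. The groups do not overlap for any gene drawn but Mup10, and Inhba averages below 1 CPM in Sham.

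On the mm10 assembly, with positions taken from the GENCODE annotation, Slc6a2 spans positions 92960079 to 93001667 of chromosome 8. Inhba lies on chromosome 13 (16011851 to 16031621), Atp2b3 on chromosome X (73503086 to 73571005) and Tnnt2 on chromosome 1 (135836354 to 135852260). Cpe lies on chromosome 8 (64592542 to 64693054, minus strand), Adora2b on chromosome 11 (62248984 to 62266453) and Efemp1 on the same chromosome (28853204 to 28926743). All of these are protein-coding genes, and the counts are given per gene symbol, so no exon or isoform is resolved.

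Extracellular matrix transcripts were higher in NeMO as groups, although almost no single member passed edgeR's test over all genes. Of 17 collagen genes 15 were higher, with a median log2 fold change of 0.54 (camera adjusted p = 0.00292, and adjusted p = 0.639 with an estimated correlation). The mean log2 CPM of these genes was 9.35 and 8.81 in NeMO replicates 3 and 4. NeMO replicates 1 and 2, at 8.40 and 8.15, lay close to the Sham libraries (8.19 to 8.36). None of the 17 passed edgeR's gene test, over all genes or adjusted over the list alone (7 higher and 1 lower at an unadjusted p under 0.05), or DESeq2's. Col3a1, a fibrillar collagen, measured 5852 ± 3299 CPM in NeMO and 3839 ± 625 in Sham (log2 fold change 0.72, SE 0.32, edgeR adjusted p = 0.275). Col1a1 measured 3016 ± 1607 and 2215 ± 371 (0.47, SE 0.36, edgeR adjusted p = 0.523). Col1a2 measured 4066 ± 2294 and 2949 ± 506 (0.53, SE 0.35). Without NeMO replicate 3 these log2 fold changes were 0.20 for Col3a1, −0.07 for Col1a1 and −0.05 for Col1a2, and without NeMO replicate 1 they were 0.72 for Col1a1 and 0.80 for Col1a2. Of 32 elastic fibre and matrix glycoprotein genes 26 were higher, with a median of 0.44 (camera adjusted p = 6.2e-04, and adjusted p = 0.639 with an estimated correlation). In that list edgeR had 0 that rose, 1 that fell (Efemp1) and 31 that did not pass (11 higher and 2 lower at an unadjusted p under 0.05). Adjusted over the list alone 7 rose and 2 fell, and with DESeq2 over all genes also 7 and 2. Fibronectin, Fn1, measured 3979 ± 1237 CPM against 1483 ± 131 (log2 fold change 1.45, SE 0.24, edgeR adjusted p = 0.0691). The elastic fibre gene Mfap4 measured 230 ± 80.9 against 93.0 ± 21.5 (1.47, SE 0.19, edgeR adjusted p = 0.0512) and Eln 215 ± 101 against 77.4 ± 12.2 (1.52, SE 0.35, edgeR adjusted p = 0.119).

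Basement membrane genes had a median log2 fold change of 0.19 with 17 of 20 higher (camera adjusted p = 0.00619, and adjusted p = 0.639 with an estimated correlation). Their most abundant members were the type IV collagens Col4a1 (0.82, SE 0.24, edgeR adjusted p = 0.145) and Col4a2 (0.77, SE 0.26). Matrix crosslinking and turnover genes had a median of 0.30 with 24 of 33 higher (camera adjusted p = 0.00619, and adjusted p = 0.652 with an estimated correlation). The most abundant members of that list were near 0, with Timp2 at −0.02 (SE 0.10) and Serpinh1 at −0.07 (SE 0.27). None of the genes in either list passed edgeR's test over all genes (7 and 10 higher and 1 and 1 lower at an unadjusted p under 0.05), and adjusted over the list alone 0 and 1 rose and none fell. With DESeq2 4 basement membrane genes rose and 0 fell, and 6 crosslinking and turnover genes rose and 1 fell. Within batches the collagen median was 0.70 in batch 1 and 0.26 in batch 2 (camera adjusted p = 0.437), and the glycoprotein median 0.52 and 0.32 (camera adjusted p = 0.166 in batch 2). In batch 2 the basement membrane median was 0.27 and the crosslinking median 0.07 (camera adjusted p = 0.0742 and 0.997), and without Sham replicate 4 the crosslinking median was 0.46. Without NeMO replicate 3 the medians were 0.22 for collagens, 0.15 for glycoproteins and 0.08 for crosslinking genes, none past the threshold (camera adjusted p = 0.116, 0.0788 and 0.116).

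Genes of the TGF-beta and BMP pathways, which control matrix production and cell growth, were higher as a list, with 24 of 32 members higher and a median log2 fold change of 0.13 (camera adjusted p = 0.00292, and adjusted p = 0.639 with an estimated correlation). Of these, 1 rose (Inhba), 0 fell and 31 did not pass in edgeR (9 higher and 0 lower at an unadjusted p under 0.05). Adjusted over the list alone 8 rose and 0 fell, and with DESeq2 over all genes also 8 and 0. Tgfb1 itself did not pass (mean 36.8 CPM in NeMO and 35.7 in Sham, log2 fold change 0.03, SE 0.17), while Tgfb2 measured 46.0 ± 7.25 against 30.5 ± 2.84 CPM (0.62, SE 0.12, edgeR adjusted p = 0.0786). Targets of the stretch-responsive factors YAP and MRTF had a median of 0.28 with 19 of 24 higher (camera adjusted p = 1.07e-04, and adjusted p = 0.639 with an estimated correlation). None of the 24 passed edgeR's test over all genes (9 higher and 0 lower at an unadjusted p under 0.05), while 5 rose with DESeq2. In edgeR 5 rose when adjusted over the list alone, led by Ptpn14 at 0.51 (SE 0.08, edgeR adjusted p = 0.0668). The abundant members Actb (−0.14, SE 0.15) and Fhl1 (0.24, SE 0.19) stood on either side of 0. The p53 and senescence list was also higher, with a median of 0.16 and 16 of 20 members higher (camera adjusted p = 0.0137, and adjusted p = 0.639 with an estimated correlation). Its abundant members were Perp at 0.02 (SE 0.10) and Ccng1 at 0.17 (SE 0.09), and 0 passed edgeR in either count (4 higher at an unadjusted p under 0.05), while 2 rose with DESeq2. In batch 2 alone the medians were 0.10 for TGF-beta genes, 0.24 for YAP targets and 0.07 for p53 genes, none past the threshold (camera adjusted p = 0.588, 0.104 and 0.680). Without Sham replicate 4 the TGF-beta median was 0.24. The p53 call also ended without NeMO replicate 3 (0.15, camera adjusted p = 0.116) or Sham replicate 3 (0.11, camera adjusted p = 0.0636).

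**Figure D2:**
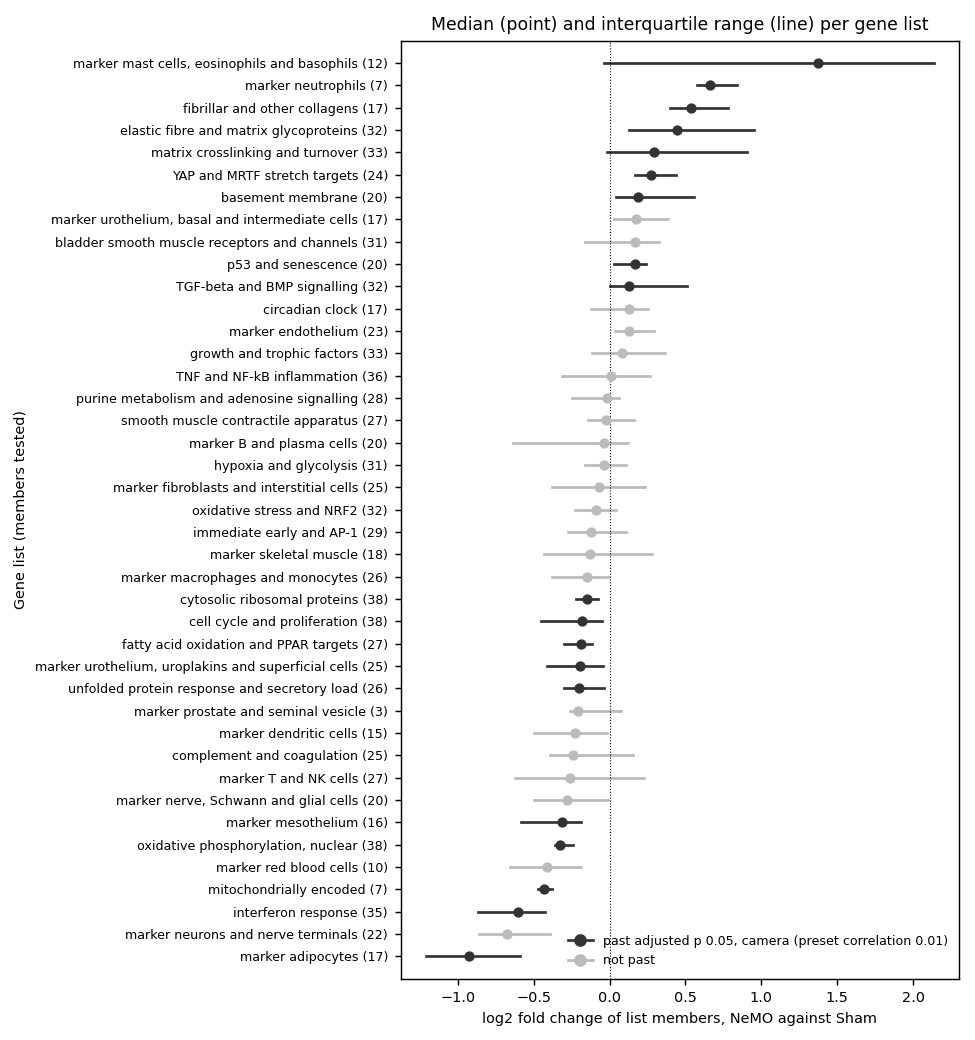
Median log2 fold change, NeMO against Sham (point), and interquartile range of the members (line) for each of the 41 gene lists tested, ordered by median, with dark for lists past camera's threshold at the preset correlation and grey for the others. Mast cell, neutrophil and collagen lists have the highest medians (1.37, 0.66 and 0.54), and the adipocyte list the lowest (−0.92).

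Transcripts for mitochondrial respiration were lower in NeMO as groups, although no single member passed edgeR's test over all genes. All 38 nuclear genes of oxidative phosphorylation were lower, with a median log2 fold change of −0.33 (camera adjusted p = 1.5e-15, and adjusted p = 0.639 with an estimated correlation). None passed edgeR's test over all genes (34 lower at an unadjusted p under 0.05), while 13 fell with DESeq2. In edgeR 34 fell and none rose when adjusted over the list alone. The mean log2 CPM of these genes was 6.67 in NeMO replicates 1, 2 and 4 and 6.43 in NeMO replicate 3. Sham replicate 1, at 6.69, lay close to NeMO replicates 1, 2 and 4. Sham replicates 2 to 4 stood at 6.92 to 7.05. Cox6c, a subunit of cytochrome c oxidase, measured 117 ± 24.6 CPM in NeMO and 199 ± 20.8 in Sham (−0.80, SE 0.15, edgeR adjusted p = 0.0786), and the ATP synthase genes Atp5b and Atp5a1 stood at −0.29 (SE 0.11) and −0.24 (SE 0.10). The 7 tested genes of the mitochondrial genome were lower as well, with a median of −0.44 (camera adjusted p = 0.00173, and adjusted p = 0.639 with an estimated correlation). Among them were mt-Co1 (−0.47, SE 0.19, edgeR adjusted p = 0.224) and mt-Cytb (−0.39, SE 0.20). None of the 7 passed edgeR, over all genes or adjusted over the list alone (4 lower at an unadjusted p under 0.05), or DESeq2, and their median was −0.66 without NeMO replicate 1 and −0.26 without NeMO replicate 3. Mitochondrial genes took 2.08 ± 0.493% of counts in NeMO and 2.88 ± 0.235% in Sham (n = 4 each, two-sided exact permutation p = 0.0571, and 0.171 after adjustment over 6 library quantities).

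Fatty acid oxidation genes and targets of the PPAR receptors, taken as 1 list, were lower with a median log2 fold change of −0.19, 23 of 27 members being lower (camera adjusted p = 6.1e-05, and adjusted p = 0.639 with an estimated correlation). Of these, 0 passed edgeR over all genes (14 lower at an unadjusted p under 0.05), 2 fell adjusted over the list alone, and 2 fell with DESeq2. The abundant member Hadha stood at −0.18 (SE 0.07). Adipocyte markers moved the same way, with a median of −0.92 and all 17 members lower. Cytosolic ribosomal protein genes had a median of −0.15 with 35 of 38 lower (camera adjusted p = 1.8e-05, and adjusted p = 0.639 with an estimated correlation). Rpl4 stood at −0.17 (SE 0.10) and Rps3 at −0.20 (SE 0.09), and none passed edgeR over all genes or adjusted over the list alone (11 lower at an unadjusted p under 0.05), while 2 fell with DESeq2. Ribosomal protein and respiratory chain genes have many near-identical pseudogenes, so the levels of single members are uncertain. In batch 2 alone the median of the fatty acid and PPAR list was −0.19 (camera adjusted p = 0.0599) and the ribosomal protein median −0.08 (camera adjusted p = 0.505). Unfolded protein response genes had a median of −0.20 (camera adjusted p = 0.0431, and adjusted p = 0.728 with an estimated correlation). The chaperone genes Hsp90b1 and Canx both stood at −0.04 (SE 0.09), and none passed edgeR in either count (2 higher and 5 lower at an unadjusted p under 0.05), while 1 fell with DESeq2. In the batches alone that median was −0.01 (batch 1, camera adjusted p = 0.725) and −0.47 (batch 2). The call ended without the batch term (−0.14, camera adjusted p = 0.209), and without NeMO replicate 2 (−0.13), Sham replicate 2 (−0.16) or Sham replicate 4 (−0.01, camera adjusted p = 0.203, 0.0798 and 0.636).

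A trend with transcript length ran through the libraries beside these groups. The correlation across genes between transcript length and a library's deviation from the gene mean ran from 0.002 to 0.261 in NeMO and from −0.267 to −0.002 in Sham (exact permutation p = 0.0286, the smallest that 4 against 4 allows, and 0.171 after adjustment over 6 quantities). The median log2 fold change rose with transcript length from −0.16 in the shortest of 8 length bins to 0.16 in the longest, with a Spearman correlation of 0.324 across genes, which are not independent replicates. Respiratory chain and ribosomal protein genes are short (median longest transcript 1306 and 1114.5 nucleotides), and collagen and basement membrane genes are long (5595 and 6631.5). After a correction for length and GC content, chosen after this trend was seen, the ribosomal protein median was −0.05 (camera adjusted p = 0.111) and the basement membrane median 0.06 (camera adjusted p = 0.152), both no longer past the threshold. The oxidative phosphorylation median was −0.21 (camera adjusted p = 9.6e-11) and the collagen median 0.46 (camera adjusted p = 0.00721).

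**Figure D3:**
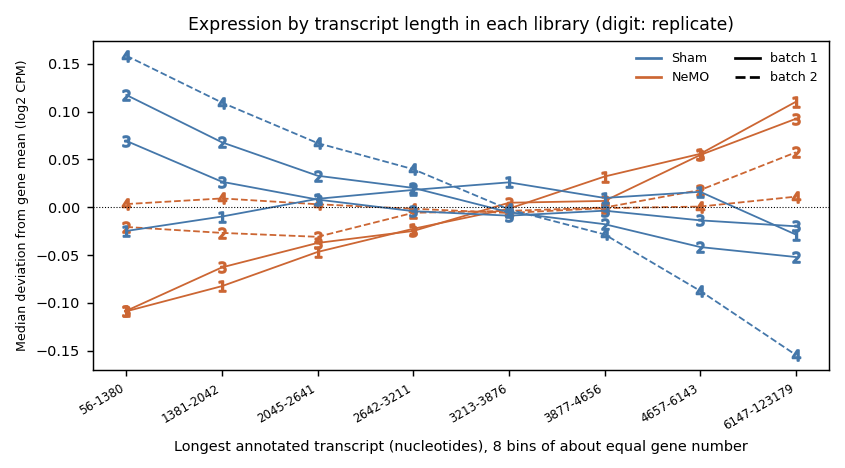
Median deviation from each gene's mean (log2 CPM) against the length of the longest annotated transcript, in 8 bins, 1 line per library, where solid lines are batch 1, dashed lines batch 2, and digits are replicate numbers. The Sham replicate 4 line falls from 0.158 to −0.154 and the NeMO replicate 1 line climbs from −0.109 to 0.110.

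Interferon response genes were lower in all 35 members, with a median log2 fold change of −0.61 (camera adjusted p = 3.4e-05, and adjusted p = 0.652 with an estimated correlation). None passed edgeR's test over all genes (6 lower at an unadjusted p under 0.05), 1 fell adjusted over the list alone, and 1 fell with DESeq2. The interferon-induced gene Ifi27l2a measured 53.1 ± 7.15 CPM in NeMO and 89.7 ± 13.7 in Sham (−0.80, SE 0.12, edgeR adjusted p = 0.0534), and the antigen presentation genes B2m and H2-K1 stood at −0.60 (SE 0.22) and −0.45 (SE 0.19). Sham replicate 1 stood above the other Sham libraries, with 20.9 CPM of the ubiquitin-like modifier gene Isg15 where the others held 6.27 to 7.22. Without Sham replicate 1 the list median was −0.21, and the list still passed at the preset correlation (camera adjusted p = 1.7e-04). In that fit B2m, H2-K1 and Isg15 stood at −0.40, −0.25 and −0.53. The median was −0.75 in batch 1 (camera adjusted p = 2.9e-04), where Sham replicate 1 had a list mean of 6.634 log2 CPM. Sham replicates 2 and 3 there stood at 5.098 and 5.224, and NeMO replicates 1 and 3 at 4.961 and 5.215. The batch 1 difference thus came mainly from Sham replicate 1. In batch 2, where that library is absent and the single Sham library is replicate 4, the median was −0.51. Mast cell, eosinophil and basophil markers had the highest median of any list, 1.37, with 9 of 12 higher (camera adjusted p = 0.00292, and adjusted p = 0.639 with an estimated correlation). Adjusted over the list alone 7 rose and 1 fell, against none over all genes in edgeR (7 higher and 1 lower at an unadjusted p under 0.05), and with DESeq2 6 rose and 1 fell. The mast cell proteases Cpa3 (4.91-fold higher, log2 fold change 2.30, SE 0.40, edgeR adjusted p = 0.0751) and Cma1 (9.14 ± 4.53 against 2.75 ± 0.389 CPM, log2 fold change 1.77, SE 0.39, edgeR adjusted p = 0.0994) were among them. The more widely expressed members Kit and Gata2 stood at −0.74 (SE 0.35) and −0.17 (SE 0.10). In batch 2 alone the mast cell median was 1.89 (camera adjusted p = 0.0643).

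Neutrophil markers had a median log2 fold change of 0.66 over the 7 of 18 that were tested, all higher (camera adjusted p = 0.0430, and adjusted p = 0.639 with an estimated correlation). None passed edgeR in either count (2 higher at an unadjusted p under 0.05), and 1 rose with DESeq2. Their mean log2 CPM was low, at 1.21 to 2.04 in NeMO replicates 2 to 4 and 0.26 to 0.83 in Sham. NeMO replicate 1, at 0.24, was the lowest library, so the markers were not higher in every NeMO library. Padi4 stood at 0.52 (SE 0.17) and Il1r2 at 0.78 (SE 0.56), and without NeMO replicate 3 they were at 0.25 and 0.16. Without NeMO replicate 1 the median was 1.11. The median was 1.14 in batch 2, and the call ended in batch 1 alone (0.58, camera adjusted p = 0.178), with the stricter filter (0.65, camera adjusted p = 0.109) and without NeMO replicate 2 (0.66), NeMO replicate 3 (0.18) or Sham replicate 4 (0.58, camera adjusted p = 0.0854, 0.350 and 0.134). TNF and NF-kB genes were not past the threshold (median 0.01, mean −0.06, camera adjusted p = 0.713), with the chemokine gene Cxcl12 at −0.57 (SE 0.12, edgeR adjusted p = 0.0880) and Nfkb1 at 0.18 (SE 0.09), and adjusted over the list alone 1 fell. Over all genes 0 passed edgeR (2 higher and 3 lower at an unadjusted p under 0.05), and with DESeq2 1 rose and 1 fell. Markers of macrophages and monocytes did not pass either (median −0.15, camera adjusted p = 0.184), with Lyz2 at −0.22 (SE 0.26) and Gpnmb at 0.25 (SE 0.10). Markers of T and NK cells, B and plasma cells and dendritic cells had medians of −0.26, −0.03 and −0.23, none past the threshold (camera adjusted p = 0.304, 0.347 and 0.0587). Without Sham replicate 1 the T and NK median was 0.13 and the dendritic cell median −0.03 (camera adjusted p = 0.967 and 0.266). Complement and coagulation genes had a median of −0.24 (camera adjusted p = 0.217), and adjusted over the list alone 3 rose and 3 fell. Over all genes 0 of them passed edgeR (4 higher and 8 lower at an unadjusted p under 0.05), and with DESeq2 3 rose and 4 fell. Adjusted over the list alone 1 dendritic cell marker fell, and none of the macrophage, T cell or B cell markers passed. Over all genes 0 markers of these 4 lists passed edgeR, with 2, 1, 0 and 0 higher and 4, 2, 1 and 1 lower at an unadjusted p under 0.05 (macrophages, T and NK, B and plasma, dendritic). With DESeq2 1 macrophage marker rose, and 2 T and NK, 1 B and plasma and 1 dendritic cell marker fell.

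**Figure D4:**
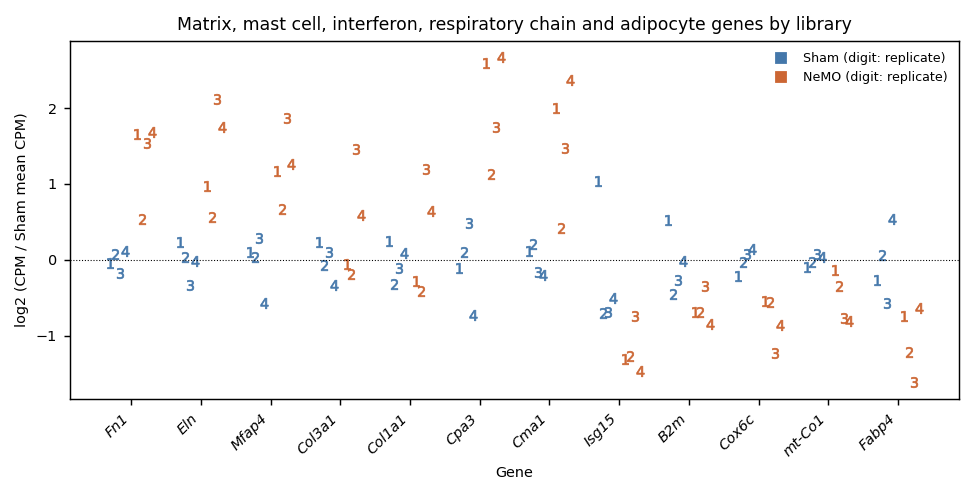
Log2 ratio of CPM to the mean of the 4 Sham libraries for 12 genes of the matrix, mast cell, interferon, respiratory chain and adipocyte groups, with digits for replicate numbers. NeMO replicate 3 is the highest library for Col3a1 and Col1a1, and Sham replicate 1 is the highest for Isg15.

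Among cell type markers, those of adipocytes were lower in all 17 members, with a median log2 fold change of −0.92 (camera adjusted p = 2.1e-06, and adjusted p = 0.639 with an estimated correlation). None passed edgeR's test over all genes (9 lower at an unadjusted p under 0.05), 3 fell adjusted over the list alone, and 5 fell with DESeq2. The fatty acid binding protein gene Fabp4 measured 310 ± 91.5 CPM in NeMO and 617 ± 207 in Sham (−1.07, SE 0.25, edgeR adjusted p = 0.109), and Scd1 stood at −0.89 (SE 0.47). Without NeMO replicate 1 the adipocyte median was −1.68 and Scd1 also at −1.68, and without NeMO replicate 3 Scd1 was at −0.55. Markers of uroplakin-bearing superficial urothelium had a median of −0.19 with 20 of 25 lower (camera adjusted p = 2.1e-04, and adjusted p = 0.639 with an estimated correlation). Of these, 0 passed edgeR over all genes (9 lower at an unadjusted p under 0.05), 8 fell adjusted over the list alone, and 7 fell with DESeq2. The uroplakin genes Upk1a and Upk2 stood at −0.48 (SE 0.12, edgeR adjusted p = 0.105) and −0.43 (SE 0.09, edgeR adjusted p = 0.0828), Upk1b at −0.28 (SE 0.13), with the superficial-cell keratin gene Krt20 at −0.75 (SE 0.16, edgeR adjusted p = 0.0899). Basal and intermediate urothelial markers had a median of 0.18 (camera adjusted p = 0.0587). Of these, 3 rose and 1 fell adjusted over the list alone, against 0 over all genes in edgeR (3 higher and 1 lower at an unadjusted p under 0.05), and 3 rose with DESeq2. The hemidesmosome gene Col17a1 stood at 1.17 (SE 0.29, edgeR adjusted p = 0.126), and at 0.73 without NeMO replicate 3 (edgeR adjusted p = 0.278). Mesothelial markers, several of which are keratin or uroplakin genes shared with urothelium, had a median of −0.31 with 13 of 16 lower (camera adjusted p = 0.00619, and adjusted p = 0.652 with an estimated correlation). Of these, 3 fell adjusted over the list alone, 0 passed edgeR over all genes (6 lower at an unadjusted p under 0.05) and 3 fell with DESeq2, with Krt18 at −0.30 (SE 0.11). That call ended without Sham replicate 2 (−0.16, camera adjusted p = 0.104). Without the batch term the superficial urothelial median was −0.09 and did not pass (camera adjusted p = 0.0550). In batch 2 alone the superficial urothelial and mesothelial medians were −0.16 and −0.10 (camera adjusted p = 0.104 and 0.206).

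Markers of neurons and nerve terminals were lower in 19 of 22 tested members, with a median log2 fold change of −0.68, but the list did not pass (camera adjusted p = 0.0957). The median was −0.36 in batch 1 (camera adjusted p = 0.938) and −1.18 in batch 2, where the single Sham library had the highest mean log2 CPM of these markers of any library (2.17). In this list edgeR had 1 gene that rose (Slc6a2), 0 that fell and 21 that did not pass (2 higher and 3 lower at an unadjusted p under 0.05). Adjusted over the list alone 1 rose, and with DESeq2 1 rose and 0 fell. Schwann cell and glial markers had a median of −0.28 (camera adjusted p = 0.0562), with Pmp22 at −0.28 (SE 0.11) and Erbb3 at 0.06 (SE 0.07). Fibroblast and interstitial cell markers had a median of −0.07 and endothelial markers 0.13, neither past the threshold (camera adjusted p = 0.429 and 0.0599). Skeletal muscle and red blood cell markers had medians of −0.13 and −0.41 (camera adjusted p = 0.189 and 0.0562), and 1 skeletal muscle marker fell adjusted over the list alone. Of Schwann, fibroblast, endothelial, skeletal muscle and red blood cell markers 0 passed edgeR over all genes, with 0, 3, 3, 0 and 0 higher and 5, 5, 1, 2 and 1 lower at an unadjusted p under 0.05. With DESeq2 1 fibroblast and 1 endothelial marker rose, and 3 fibroblast, 1 skeletal muscle and 1 red blood cell marker fell. Of 18 prostate and seminal vesicle markers only 3 were tested, with a median of −0.21 (camera adjusted p = 0.980). Xist was counted 17790 to 36201 times per library and the Y-linked genes 0 to 3 times, in every library of both groups.

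Contractile genes of smooth muscle did not pass as a group, with a median log2 fold change of −0.03 over 27 members (camera adjusted p = 0.471). None of them passed edgeR in either count (0 higher and 2 lower at an unadjusted p under 0.05), and 1 fell with DESeq2. Smooth muscle myosin, Myh11, measured 13066 ± 4234 CPM in NeMO and 12736 ± 1209 in Sham (0.06, SE 0.25). Smooth muscle actin, Acta2, measured 6172 ± 1256 and 6450 ± 1040 (−0.11, SE 0.19), and filamin A, Flna, 9423 ± 2189 and 8209 ± 655 (0.21, SE 0.20). Pcp4, a calmodulin-binding gene of the list, stood at −1.93 (SE 0.54, edgeR adjusted p = 0.157). Without NeMO replicate 1 Myh11 was at −0.29 and Flna at −0.03, and without NeMO replicate 3 they were at 0.31 and 0.37. Without NeMO replicate 3 the contractile median was 0.14 and passed upward (camera adjusted p = 0.0317). Without NeMO replicate 1 it was −0.29 and passed downward (camera adjusted p = 6.8e-05). NeMO replicates 1 and 3 were the highest and lowest libraries for this list, so both calls rest on single libraries. Receptors and channels of bladder muscle had a median of 0.17 (camera adjusted p = 0.191), with 0 past edgeR's test over all genes (7 higher and 3 lower at an unadjusted p under 0.05) and 4 up and 2 down adjusted over the list alone. With DESeq2 also 4 rose and 2 fell. The BK channel gene Kcnma1 stood at 0.56 (SE 0.09, edgeR adjusted p = 0.0677) and the muscarinic receptor gene Chrm3 at 0.30 (SE 0.29). The calcium pump gene Atp2a2 stood at −0.12 (SE 0.18) and the purine receptor gene P2rx1 at −0.15 (SE 0.26). With 1 library left out, Chrm3 ran from −0.01 to 0.54, Atp2a2 from −0.41 to 0.06 and P2rx1 from −0.60 to 0.12.

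Cell cycle genes were lower in 30 of 38 members, with a median log2 fold change of −0.18 (camera adjusted p = 0.00292, and adjusted p = 0.639 with an estimated correlation), and none passed edgeR over all genes or adjusted over the list alone (7 lower at an unadjusted p under 0.05), while 1 fell with DESeq2. The abundant members Ccnd1 and Rrm1 stood at 0.27 (SE 0.16) and −0.05 (SE 0.07), and the median was −0.30 in batch 1 and 0.03 in batch 2 (camera adjusted p = 0.837 in batch 2). It was −0.30 without Sham replicate 4 and −0.47 without the batch term. Immediate early genes had a median of −0.12 (camera adjusted p = 0.191), with 0.07 in batch 1 (camera adjusted p = 0.524) and −0.53 in batch 2 against its single Sham library. They included Fos at −1.13 (SE 0.34, edgeR adjusted p = 0.170) and Jun at −0.28 (SE 0.30). Fos was at −0.70 without Sham replicate 4, and Jun ran from −0.67 to 0.08 with 1 library left out. None of the immediate early genes passed edgeR in either count (1 higher and 2 lower at an unadjusted p under 0.05), and with DESeq2 1 rose and 1 fell. Myc stood at −0.21 (SE 0.14), Fosl2 at 0.32 (SE 0.10) and Klf6 at 0.11 (SE 0.09). Growth and trophic factors (median 0.08, camera adjusted p = 0.369, 1 up and 1 down adjusted over the list alone) included Bdnf at 1.65 (SE 0.33, edgeR adjusted p = 0.0850). Over all genes 0 of them passed edgeR (5 higher and 4 lower at an unadjusted p under 0.05), and with DESeq2 1 rose and 3 fell. Hbegf stood at 0.03 (SE 0.24), Igfbp2 at 0.25 (SE 0.31) and Igfbp7 at 0.19 (SE 0.18). The purine and adenosine list did not pass (−0.02, camera adjusted p = 0.233), with 1 gene that fell (Adora2b), 0 that rose and 27 that did not pass in edgeR (2 higher and 6 lower at an unadjusted p under 0.05), and 1 up and 4 down adjusted over the list alone. With DESeq2 1 rose and 3 fell. Lists of hypoxia and glycolysis, oxidative stress and the circadian clock had medians of −0.04, −0.09 and 0.13 and did not pass (camera adjusted p = 0.741, 0.0843 and 0.447). In edgeR 0 of their members passed in either count, with 3, 2 and 1 higher and 0, 10 and 0 lower at an unadjusted p under 0.05. With DESeq2 1 hypoxia gene rose, and 2 oxidative stress genes rose and 2 fell. Tnf stood at 0.64 (SE 0.57), at under 1 CPM in both groups, and Gapdh at −0.33 (SE 0.26) from only 3.22 ± 0.864 and 3.92 ± 0.595 CPM. Nppb had 0 counts in every library, so no fold was taken.

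Other splits of the 8 libraries into 4 and 4 gave 7 to 26 lists past camera at its preset correlation of 0.01. Of the 41 lists tested, 19 passed it in the real comparison, 9 higher and 10 lower. With an estimated correlation 0 passed (1 at an unadjusted p under 0.05), and 0 passed fry's test of whether the genes of a list move, on balance, one way (7 at an unadjusted p under 0.05). In fry's test of change in either direction 15 lists passed, and they were not all among the 19. Muscle receptors and channels, growth factors, complement, oxidative stress and purine genes passed it without a camera call. Lists that camera called but this test did not were collagens, basement membrane, crosslinking, interferon response, mitochondrial genome, unfolded protein response, neutrophils, adipocytes and mesothelium.

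Camera values for left-out libraries and single batches all use the preset correlation of 0.01. Those fits were not run with an estimated correlation, with which 0 lists passed on all libraries. Several lists that missed the threshold with all libraries passed camera at the preset correlation when 1 library was left out. Without NeMO replicate 1 these were neurons (−1.02, camera adjusted p = 0.0110), immediate early genes (−0.35, camera adjusted p = 9.1e-04), hypoxia genes (−0.16, camera adjusted p = 0.0110), Schwann cells (−0.25, camera adjusted p = 0.0430), red blood cells (−0.59, camera adjusted p = 0.0205), basal urothelium (0.17, camera adjusted p = 0.0132) and endothelium (0.24, camera adjusted p = 0.0177). Without NeMO replicate 2 they were endothelium (0.24, camera adjusted p = 2.0e-04) and red blood cells (−0.65, camera adjusted p = 0.00247). Without NeMO replicate 3 they were macrophages (−0.36, camera adjusted p = 0.0114), T and NK cells (−0.56, camera adjusted p = 0.00337), dendritic cells (−0.66, camera adjusted p = 0.00137) and oxidative stress genes (−0.16, camera adjusted p = 0.0189). Without NeMO replicate 4 they were macrophages (−0.29, camera adjusted p = 0.0277), dendritic cells (−0.30, camera adjusted p = 0.0198), Schwann cells (−0.28, camera adjusted p = 0.0361), skeletal muscle (−0.39, camera adjusted p = 0.0164), complement (−0.32, camera adjusted p = 0.0422) and basal urothelium (0.25, camera adjusted p = 0.0422).

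Among Sham libraries, leaving out replicate 1 brought red blood cell markers past the threshold (−0.50, camera adjusted p = 0.0363). Leaving out Sham replicate 2 did so for neurons (−0.96, camera adjusted p = 3.0e-05), Schwann cells (−0.40, camera adjusted p = 0.00986), dendritic cells (−0.32, camera adjusted p = 0.0147), T and NK cells (−0.30, camera adjusted p = 0.0465) and basal urothelium (0.21, camera adjusted p = 0.0246). Leaving out Sham replicate 3 did so for dendritic cells (−0.23, camera adjusted p = 0.0294), immediate early genes (−0.22, camera adjusted p = 0.0240) and oxidative stress genes (−0.12, camera adjusted p = 0.0445). Leaving out Sham replicate 4, which leaves the comparison within batch 1, did so for endothelium (0.31, camera adjusted p = 2.6e-04), red blood cells (−0.51, camera adjusted p = 0.0202), muscle receptors and channels (0.20, camera adjusted p = 0.0305) and basal urothelium (0.25, camera adjusted p = 0.0287). In the fit of batch 1 alone the first 3 of these passed too, and basal urothelium did not (0.25, camera adjusted p = 0.0545). Against the single Sham library of batch 2 the medians were −0.11 for endothelium, −0.24 for red blood cells, −0.06 for receptors and channels, −0.57 for dendritic cells and −0.27 for hypoxia genes. Whether the batches differ was not tested.

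Some named genes that missed the threshold with all libraries passed edgeR's test when 1 library was left out. Without NeMO replicate 1 these were Fn1, Mfap4, Cox6c, Ifi27l2a, Ptpn14, Kcnma1, Tgfb2, Fabp4, mt-Co1, Padi4, Fosl2, Postn, Mrgprb1, Adipoq and Col17a1, with edgeR adjusted p from 0.00134 (Col17a1, log2 fold change 1.48) to 0.0489 (mt-Co1, −0.67). Without NeMO replicate 2 they were Fn1, Mfap4, Ifi27l2a, Tgfb2, Cpa3, Cma1, Tpsb2 and Mrgprb1, with edgeR adjusted p of at most 0.0498 (Mrgprb1, 2.24).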

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

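The tests of NeMO replicate 3 alone, Sham replicate 1 alone and a larger share of fibroblasts were chosen only after the results were seen, as was the length and GC correction. In 302 groups of 4 libraries, 1 library stood far from the other 3 in 19, where chance alone would give 15.1, since chance picks about 1 in 20 groups. Their number is close to that of chance.

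Among NeMO libraries, replicate 1 held 945 CPM of Timp2 (others 773 to 800.0) and 426 CPM of H2-K1 (others 496 to 510). NeMO replicate 3 held 57.3 CPM of Rrm1 (others 52.7 to 53.1), 782 CPM of Atp5a1 (others 931 to 957) and 74.7 CPM of Grem1 (others 1.29 to 13.8). Among Sham libraries, replicate 1 held 432 CPM of Igfbp7 (others 490 to 495), 377 CPM of Lyz2 (others 248 to 267), 20.9 CPM of Isg15 (others 6.27 to 7.22) and 29.1 CPM of Cxcl10 (others 1.14 to 2.24). Sham replicate 3 held 14546 CPM of Myh11 (others 12045 to 12223) and Sham replicate 4 held 47.9 CPM of Tgfb1 (others 29.7 to 32.8).

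The mean log2 CPM of a list stood apart in 6 cases. For muscle receptors and channels Sham replicate 3 was at 5.48 (others 5.33 to 5.34), for YAP and MRTF targets it was at 5.77 (others 6.19 to 6.20), and for B and plasma cell markers at 1.25 (others 0.92 to 0.95). Sham replicate 1 was at 6.63 for interferon response genes (others 5.10 to 5.30), NeMO replicate 2 at 5.17 for complement genes (others 5.72 to 5.73), and NeMO replicate 3 at 6.43 for nuclear oxidative phosphorylation genes (others 6.67 to 6.67). NeMO replicate 2 had 20260 genes detected, against 20741 to 20814 in the other NeMO libraries. The correlation between GC content and deviation from the gene mean was 0.334 in NeMO replicate 4 (others −0.186 to −0.122), and it was also 0.334 in Sham replicate 4.

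By the share of all splits, chance could not be excluded for either total. Of the 35 splits of the 8 libraries into 4 and 4, 3 gave as many genes as the real 12. The highest other gave 79 genes. For lists, 11 gave as many as the real 19, and the other splits gave 7 to 26. Camera at its preset correlation thus called lists in every split. A list call there does not by itself set NeMO apart from Sham. The split with 79 genes set NeMO replicates 1 and 3 and Sham replicates 2 and 3 against batch 2 with Sham replicate 1, and a split with 47 genes set NeMO replicate 1 and the batch 1 Sham libraries against batch 2 with NeMO replicate 3. In both, every batch 2 library lies on 1 side, so with batch in the model these contrasts come down to a single batch 1 library against the other 4, which points to a structure of single libraries. Of the 30 splits with batch 2 libraries on both sides, a selection made after the result was seen, 1 gave as many genes (the real one, highest other 2) and 10 as many lists (highest other 26). The gene total therefore rests on which splits are counted, and chance is left open for it. Within batch 1 the real comparison gave 0 genes, with 1756 at an unadjusted p under 0.05 in edgeR.

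Lower oxidative phosphorylation and ribosomal protein transcripts in NeMO were weighed against the trend with transcript length and GC content. The bootstrap intervals here and below are of a median over genes, which are not independent replicates. They do not measure the spread between libraries. After the correction the oxidative phosphorylation median was −0.21 (95% bootstrap interval −0.26 to −0.18, before −0.33). In these libraries that argues against the fitted trend as the whole cause. The ribosomal protein median was −0.0452 after the correction (−0.09 to 0.01, before −0.15), so the trend may account for that change. A biological reading of the respiratory chain change stays a hypothesis, with chance open.

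Higher collagen and matrix glycoprotein transcripts (49 genes, median 0.50) had a median of 0.46 after the length and GC correction (0.32 to 0.63). In these libraries that argues against the fitted trend as the whole cause. The 22 of 25 fibroblast and interstitial markers outside the matrix lists had a median of −0.0755 (−0.29 to 0.02), so these markers as a set were not higher. The list mixes several kinds of cells, so it cannot decide whether 1 kind of fibroblast took a larger share. Without NeMO replicate 3 the median was 0.18 (0.02 to 0.35), so how far that library carries the pattern cannot be told apart with 3 libraries left in its group. Matrix production in obstructed tissue is a candidate explanation that stays open and was not tested.

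Lower interferon response transcripts (median −0.61) stood at −0.57 after the correction (−0.80 to −0.44). In these libraries that argues against the fitted length and GC trend as the whole cause. Without Sham replicate 1 the median was −0.21 (−0.31 to −0.09), so a raised interferon response in that library may account for part of the difference. In batch 2, which does not hold that library, the median was −0.51 (batch 1 −0.75). That value rests on the single Sham library there, so it cannot decide whether Sham replicate 1 is the whole cause. Whether the rest follows from obstruction cannot be told apart from the spread of the other Sham libraries.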

How the results depend on the processing

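The threshold of 0.1 and the length and GC correction were chosen only after the results were seen, and all other alternatives were fixed before the data were examined. The count of 12 genes became 7 without the batch term (5 of them shared) and 172 with no filter (24803 genes tested). It became 865 with DESeq2's Wald test (all 12 shared), 5 with limma voom (4 shared), 0 in batch 1 alone and 291 at the threshold of 0.1. It ran from 0 (without NeMO replicate 4 or Sham replicate 4) to 652 (without NeMO replicate 1) when 1 library was left out. With 0 genes edgeR still gave 1756 (batch 1), 2549 (without NeMO replicate 4) and 1656 (without Sham replicate 4) at an unadjusted p under 0.05. The fit without Sham replicate 4, the only Sham library of batch 2, repeats the comparison within batch 1. Batch 2 alone rests on that library, so no count of genes is given for it. The cause of the other changes was not tested. DESeq2 size factors, upper-quartile scaling, a stricter filter and a non-robust fit gave 15, 14, 14 and 11 genes, and the length and GC correction 14, of which 9 were shared (Slc6a2, Adora2b and Btbd7 lost their calls). Scaling moved the median of all genes by 0.0052 and −0.0078.

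With the replicate block in place of the batch term, 0 genes passed in edgeR (2648 at an unadjusted p under 0.05), against 12. Libraries with the same number correlated at −0.0096, 0.0820, 0.0438 and 0.324, and the best Sham partners of NeMO replicates 1, 2, 3 and 4 were 3, 2, 1 and 4. The numbers thus gave no clear pairing, but so few libraries cannot exclude one. The block also moved lists: the cell cycle median was −0.42, the unfolded protein response no longer passed (−0.13, camera adjusted p = 0.0998), and neurons (−0.51, camera adjusted p = 0.00696), basal urothelium (0.25), endothelium (0.12), complement (−0.29), macrophages (−0.28), dendritic cells (−0.33) and Schwann cells (−0.35) passed.

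The count of 19 lists was 10 in batch 2 alone, 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 0 with fry (7 at an unadjusted p under 0.05). Batch 2 rests on a single Sham library, and for the other settings the cause was not tested. The count lay between 19 and 27 in every other alternative run, with some lists gained: with no filter basal urothelium (camera adjusted p = 0.0427), endothelium (camera adjusted p = 0.0458), dendritic cells (camera adjusted p = 0.0340), Schwann cells (camera adjusted p = 0.0301) and red blood cells (camera adjusted p = 0.0272), with the length and GC correction endothelium (camera adjusted p = 0.0343) and Schwann cells (camera adjusted p = 0.0284), with the stricter filter Schwann and red blood cells (camera adjusted p = 0.0475 and 0.0439), and with a prior count of 0.5 red blood cells (camera adjusted p = 0.0497). Without the batch term the calls of superficial urothelium (−0.09, camera adjusted p = 0.0550) and the unfolded protein response (−0.14, camera adjusted p = 0.209) ended, the cell cycle median was −0.47, and complement (−0.30), basal urothelium (0.17), macrophages (−0.25), dendritic cells (−0.27) and Schwann cells (−0.34) passed; the cause was not tested. The unfolded protein response median was −0.011 in batch 1 alone (camera adjusted p = 0.725) and ran from −0.22 (without Sham replicate 1) to −0.0115 (without Sham replicate 4) with 1 library left out. Matrix crosslinking had a median of 0.0663 in batch 2, where the test's direction turned (camera adjusted p = 0.997). The contractile median ran from −0.29 (without NeMO replicate 1) to 0.14 (without NeMO replicate 3). NeMO replicate 1 had the highest mean log2 CPM of this list (10.32). NeMO replicate 3 had the lowest (9.44), and Sham libraries stood at 9.77 to 10.08. Each shift thus came from the library left out.

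Over all alternatives, the genes past the threshold gave 240 values, of which 127 kept their side of it, 113 lost it and 0 reversed. Named genes not past it gave 1838, of which 98 passed and 57 changed sign. Lists past the threshold gave 361, of which 290 kept their side, 68 lost it and 3 reversed, and the other lists gave 417, of which 62 passed, 1 reversed and 34 changed sign. In simulated data the test found 26.6% of changes of 0.5 and 68.4% of changes of 1 (log2), so changes of that size can be missed with 4 libraries per group.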

Other observations

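The genes below were singled out after their values were seen, and none passed the threshold over all genes with edgeR. Their groups did not overlap, a pattern that 8.19% of the genes tested showed against 2.86% on average over random groupings. That difference does not exclude chance.

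Itgbl1 measured 34.5 ± 6.10 CPM in NeMO and 9.98 ± 3.55 in Sham (mean ± SD, n = 4 each, log2 fold change 1.85, SE 0.24, edgeR adjusted p = 0.0512). Cthrc1, a secreted collagen triple helix protein, measured 6.24 ± 3.24 and 1.20 ± 0.249 CPM (2.42, SE 0.41, edgeR adjusted p = 0.0691), and Sfrp4, a secreted Wnt-binding protein, stood at 1.58 (SE 0.29, edgeR adjusted p = 0.0850). The BMP antagonist Grem1 measured 22.8 ± 35.1 against 0.638 ± 0.443 CPM (5.45, SE 1.49, edgeR adjusted p = 0.149), with 74.7 CPM in NeMO replicate 3, and its log2 fold change was 2.47 without that library.

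The serotonin receptor gene Htr1b measured 7.47 ± 2.60 CPM in NeMO and 1.97 ± 0.211 in Sham (1.92, SE 0.28, edgeR adjusted p = 0.0534), and the adrenoceptor gene Adra1d stood at 2.18 (SE 0.39, edgeR adjusted p = 0.0691). The tachykinin receptor gene Tacr2 measured 5.38 ± 1.94 against 15.4 ± 1.97 CPM (−1.49, SE 0.26, edgeR adjusted p = 0.0691), the glutamate receptor gene Gria1 3.68 ± 2.10 against 17.7 ± 2.83 (−2.24, SE 0.40, edgeR adjusted p = 0.0786), and the galanin receptor gene Galr2 stood at −1.98 (SE 0.41, edgeR adjusted p = 0.0899). Without NeMO replicate 1 the genes named here other than Grem1 passed edgeR's test, with adjusted p from 0.00544 (Cthrc1, log2 fold change 2.82) to 0.0330 (Adra1d, 2.29). Htr1b and Adra1d also passed without NeMO replicate 2 (edgeR adjusted p = 0.0428 and 0.0342), and Itgbl1 without Sham replicate 2 (2.07, edgeR adjusted p = 0.0160) or Sham replicate 3 (1.70, edgeR adjusted p = 0.0491).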
